A study of Mus musculus with 2 samples.

How the data were processed

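Total RNA was isolated from dissected mouse retinas at postnatal day 15, and libraries were made by a commercial provider with standard Illumina methods, per the labels' protocols. The 2 samples were grouped by their labels into 1 control library (floxed Dnmt1, Dnmt3a and Dnmt3b, Rx-Cre negative) and 1 triple mutant library (the same alleles, Rx-Cre positive). The strain label reads C57BL/6 for the control and C57BL/7 for the mutant, so it differs between the genotypes; this may be an entry error, and the label was not used in any comparison. Reads were aligned to mm10 with TopHat2 2.0.8 and compared with Cuffdiff 2.1.1, per the submitters' processing notes; read layout, strandedness and the annotation used are not given in the sources used here.

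The deposited values are FPKM per RefSeq transcript in each library, as estimated by the authors, in 2 tables, per the file headers. The authors' tables also hold a log2 fold change, a p-value and a q-value for each transcript, a significance call and a status, per the file headers. The first table lists 30608 rows of transcripts with gene symbols and the second 33362 rows without symbols. They share 29873 identifiers, held by 30382 rows of the first and 30303 of the second, because a transcript placed at several loci can have more rows in 1 table than in the other. The second table came from a separate run on the same libraries: its control values were shifted by -0.04 and its mutant values by 0.02 on the log2 scale, which moves the log2 ratio by 0.06. The planned design assumed a gene-level table, but both tables list transcripts. Gene FPKM was therefore the sum over a gene's transcripts in the table with symbols. A gene was used where at least 1 transcript had status OK and none had a failed or excessive-data status. Of 23356 symbols, 15318 were used, and 6 genes with failed rows were left out, among them Plekhb1, Fam169a, Nsa2 and Ddx19b. A symbol at several loci (255 symbols) was counted but not named, except by the rule for lists. Of 14651 single-transcript loci, 99.8% overlapped the GENCODE M21 gene of the same name, and coordinates are from that annotation on GRCm38, the assembly that mm10 denotes. Of the second table's identifiers, 99.9% were matched to a symbol through the first table and RefSeq's gene table (GRCm38.p6).

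Size was measured as log2 of the ratio of mutant to control FPKM after adding a pseudocount of 1 FPKM, a scale that understates the ratio of low genes. Genes with at least 1 FPKM in at least 1 library counted as measured, and a log2 ratio of at least 1 either way as past the size rule. There was 1 library per group, so no test was run and no p-value was computed. A gene list's median was given with its percentile among 10000 random lists of the same size matched in 20 bins of mean expression, for lists with at least 5 measured genes; this describes these libraries only. The 34 lists, of cell types and programmes, were fixed before the data were examined, as were the design, the naming rule and most alternatives. Their results are all printed, except the mitochondrially encoded genes, which had 0 members in the table. Near 0 meant under 0.1 FPKM in 1 library and at least 1 in the other. Isoform use was compared where the summed FPKM was at least 5 in both libraries, and a difference in share of at least 30 points was counted.

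Genes were named by a rule: the 3 targeted genes with Tet1, Tet2, Tet3 and Uhrf1; the 12 highest and 12 lowest ratios among genes with at least 5 FPKM in the higher library and an established symbol (leaving out predicted genes, microRNAs, small nucleolar RNAs, ribosomal protein and haemoglobin genes, Y-linked genes and Xist); up to 4 genes of each list with the largest ratios either way; the 6 highest genes near 0 in each direction, with the same limit on symbols; and the 6 genes with the largest difference in isoform share. Genes named outside it (Nudt6, the small RNA genes near 0 and single genes in the closing part) were chosen after their values were seen. Of the 140 named genes, 14 overlap exons of a gene on the opposite strand that had at least 1 FPKM, and fragments of such pairs cannot be told apart unless counting used strand.

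Depth was read from the steps between the lowest values. Among single-transcript genes of at least 3000 bases, 129 of 173 low control values (74.6%) and 116 of 163 low mutant values (71.2%) were whole multiples of a common step within 10% of a step. A fragment per kilobase was worth 0.0207 FPKM in the control and 0.0177 in the mutant. A floor of 3 fragments over 2 kb was 0.031 and 0.0266 FPKM. Intervals of 95% on folds treat the fragments so recovered as counts, cover counting error only and use a fragment length of 150 bases. Of the lengths tried, this gave the largest combined share of whole multiples, so the 74.6% and 71.2% are maximised by the fit. FPKM summed to 359370 in the control and 363538 in the mutant.

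The size rule and list percentiles were tested on simulated data, drawn for 12758 genes at the depths above with 200 genes altered. The altered genes were drawn from those with a mean of at least 5 FPKM, so recovery at lower levels was not tested. All 100 genes altered by a log2 ratio of 1.5 and all 100 altered by 3 were recovered (100%). With counting error alone, 0 of 12558 unaltered genes passed. Of 100 unaltered lists of 20 genes, 3 lay outside the central range, and of 100 lists shifted by 0.3, 100 did. Alternatives covered the pseudocount, the filter, 2 rescalings, the second table, rows of any status and stricter limits. Scripts used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1.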

Results

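RNA was sequenced from the retinas of mouse pups at postnatal day 15, with 1 control library and 1 triple mutant library. Both carried loxP-flanked alleles of the 3 DNA methyltransferase genes Dnmt1, Dnmt3a and Dnmt3b. The control lacked the Rx-Cre transgene and the mutant carried it, so that Cre recombinase, expressed under regulatory sequence of the retinal transcription factor gene Rx, could remove the flanked sequence in the retinal lineage. Dnmt1 maintains DNA methylation through replication, and Dnmt3a and Dnmt3b set it at new sites. There were no replicates, so every difference below is a difference between these 2 libraries, without a replicate check or a test between genotypes. By the steps between the lowest FPKM values, an FPKM of 1 corresponded to about 48.4 fragments per kb of transcript in the control library and 56.5 in the mutant library. Over 2 kb it thus rested on about 96.7 fragments in the control and 113 in the mutant. Bracketed ranges after a fold are 95% intervals that cover counting error only.

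The targeted genes were compared first, which also checks the labels. All 3 were lower in the mutant library, and none was near 0. Dnmt1 (chromosome 9, 20907209 to 20959888, minus strand, GRCm38) stood at 21.7 FPKM in the control and 11.6 in the mutant, 53.5% of the control (51.2 to 55.8). Dnmt3a (chromosome 12, 3806007 to 3914443, plus strand) stood at 87.4 and 56.0 FPKM, 64.1% of the control (63.2 to 65.1). Dnmt3b (chromosome 2, 153649450 to 153687730, plus strand) was low in both libraries, at 1.03 and 0.827 FPKM, 80.4% of the control (65.5 to 99.5). Its log2 ratio of -0.151 lay between the quartiles of all measured genes (-0.158 and 0.146). Dnmt3b thus adds little to the check of the labels. The Dnmt1 transcript NM_001199431 had 10.9 FPKM in the control and 5.02 in the mutant, and NM_010066 had 10.2 and 6.06. Of the Dnmt3a transcripts, NM_007872 carried most of the signal, with 85.3 and 53.6 FPKM. The other 2 went opposite ways: NM_001271753 had 2.13 FPKM in the control and 0.00182 in the mutant, and NM_153743 was listed at 0 in the control and had 2.47 in the mutant. A whole-transcript FPKM also counts fragments from exons that Cre leaves in place, and the labels do not state which exons were flanked. Among related genes, the cytosine dioxygenase genes Tet1 (8.68 and 6.96 FPKM), Tet2 (11.7 and 10.1) and Tet3 (52.3 and 47.5) were slightly lower in the mutant library, and Uhrf1, whose product guides Dnmt1 to replicated DNA, had 0.197 and 0.286 FPKM. Of 15 measured genes of the DNA methylation machinery, 1 passed the size rule, the stress-responsive gene Gadd45b, with 3.90 FPKM in the control and 14.7 in the mutant.

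**Figure D1:**
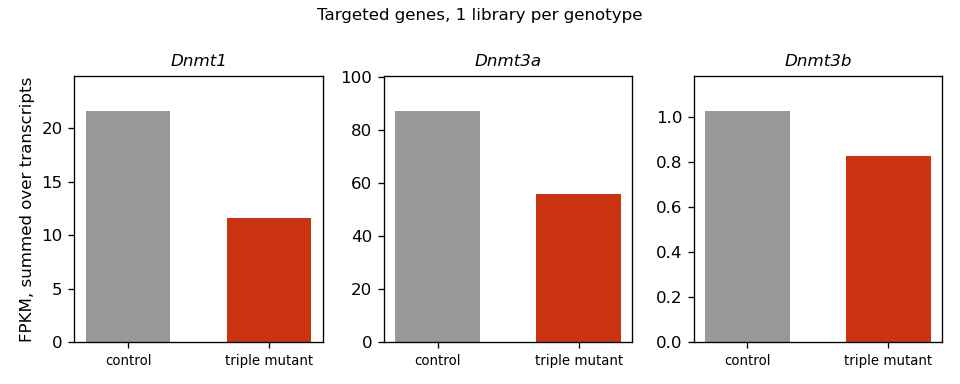
FPKM of the 3 targeted genes (vertical axis, summed over each gene's transcripts, each panel with its own scale starting at 0) in the control library and the triple mutant library, 1 library each, so the bars have no error bars. The mutant bar is 53.5% of the control bar for Dnmt1, 64.1% for Dnmt3a and 80.4% for Dnmt3b.

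The comparison of all genes asked which transcripts differed in the retina carrying Cre. Most of the 12 highest ratios belonged to genes of retinal stress, interferon response and antigen presentation; the other 3 were Prss56, Irgm1 and Pcolce. Most of the 12 lowest belonged to lens crystallins and pigment cell genes. Edn2, which encodes endothelin 2, had 0.114 FPKM in the control and 48.9 in the mutant (428-fold higher, 215 to 1103), and the serine protease gene Prss56 had 9.88 and 276 FPKM (28.0-fold, 26.2 to 29.8). Pcolce, which encodes an enhancer of procollagen cleavage, had 2.80 and 44.9 FPKM (16.1-fold, 13.9 to 18.6). Fgf2, a growth factor gene, had 2.12 and 58.4 FPKM. Its antisense neighbour Nudt6 had 3.89 and 26.6 FPKM, and whether the counting used strand is not given in the sources used here, so the 2 cannot be assigned separately. In the other direction, the lens chaperone gene Cryaa had 55.7 FPKM in the control and 0.192 in the mutant (290-fold lower, 167 to 567), and Ttr, which encodes transthyretin, had 79.1 and 2.49 FPKM (31.8-fold lower, 27.0 to 37.9). Among 13280 measured genes, 245 were higher in the mutant library by a log2 ratio of at least 1, 86 were lower, and 12949 lay between. The central 95% of log2 ratios ran from -0.63 to 0.82. Of the 245 higher genes, 43 were on the interferon or antigen presentation lists and 164 on no list. Of the 86 lower genes, 22 were on the lens or pigment epithelium lists, and 64 remained without those lists. These counts depended on the pseudocount, with 390 higher and 180 lower at 0.1 against 92 and 33 at 5.

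The interferon and antigen presentation lists had the highest medians of the 32 lists with enough measured genes, out of 34 fixed before the data were examined. Of 28 measured interferon and antiviral genes, 27 were higher by the size rule and 0 were lower, with a median log2 ratio of 2.43. Of 17 measured antigen presentation genes, 16 were higher and 0 were lower, with a median of 3.02. Each median had percentile 100 among 10000 random lists of matched expression. The ubiquitin-like modifier gene Isg15 had 1.04 FPKM in the control and 41.5 in the mutant (40.0-fold, 28.3 to 60.4), the antiviral tetherin gene Bst2 had 2.35 and 48.4, Oasl2 had 1.59 and 30.6, and Ifit1 had 0.308 and 13.2. The light chain of class I molecules, B2m, had 21.6 and 348 FPKM (16.1-fold, 14.9 to 17.3), and Cd74, the invariant chain of class II molecules, had 0.291 and 22.1 (75.8-fold, 45.8 to 131). H2-K1 had 8.03 and 158 FPKM and H2-Q4 had 1.82 and 40.1. The class I genes are near-identical copies of each other that can share fragments, so the split between them is uncertain. The size of the medians depended on the pseudocount: the interferon median was 3.57 at 0.1 and 1.09 at 5, and the antigen presentation median 4.001 and 1.94. The interferon-induced GTPase gene Irgm1, on neither list, had 1.26 and 27.1 FPKM.

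Markers of microglia and macrophages were also higher in the mutant library. Of 21 measured, 13 were higher by the size rule and 0 lower, with a median log2 ratio of 1.28 (percentile 100), which was 1.59 with a pseudocount of 0.1, 0.73 with 5 and 1.58 among genes of at least 5 FPKM. The complement genes C1qa (5.84 and 31.2 FPKM) and C1qc (5.61 and 28.8) and the lysozyme gene Lyz2 (0.851 and 10.8) led this list after Cd74. Of 20 measured genes of reactive gliosis and retinal stress, 9 were higher and 0 lower, with a median of 0.82 (percentile 100), which was 1.09, 0.52 and 1.22 in the same 3 settings. Besides Edn2 and Fgf2, the complement gene C4b had 0.0827 and 6.85 FPKM and the transcription factor gene Cebpd had 4.14 and 34.1. Of 23 measured Mueller glia markers, 1 was higher, Crym (99.4 and 323 FPKM), 2 were lower, Rgr (19.01 and 1.37), a retinoid-binding opsin gene also used in pigment epithelium, and Spc25 (74.7 and 36.3), and the median was 0.32 (percentile 100). The progenitor and cell cycle list had 1 higher gene of 12, the cyclin gene Ccnd1 (12.2 and 26.0 FPKM), and a median of 0.27 (percentile 99.7). Apoptosis and p53 genes had 0 of 22 past the size rule and a median of 0.13 (percentile 99.2), with Bmf at 11.3 and 19.2 FPKM.

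**Figure D2:**
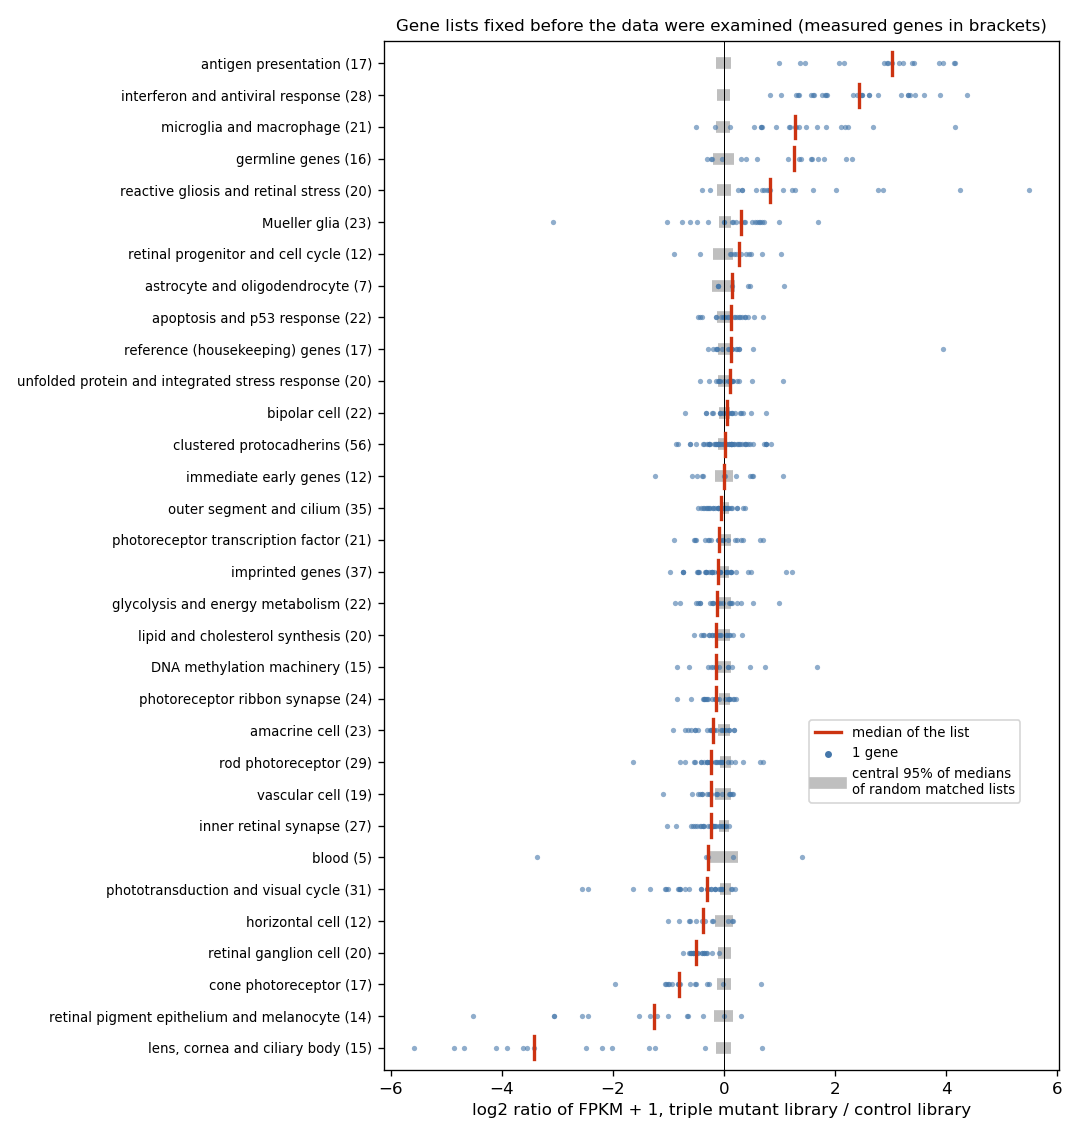
Log2 ratios of FPKM + 1 between the triple mutant and control libraries (horizontal axis) for the measured genes of each list with at least 5 such genes (rows, number of genes in brackets). Blue points are genes, red marks are list medians, and grey bars are the central 95% of medians of 10000 random lists matched on expression; the medians run from -3.41 for lens, cornea and ciliary body genes to 3.02 for antigen presentation genes.

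Germline genes, several of which are known to be silenced by DNA methylation in somatic cells, were higher in the mutant library at low levels. Of 53 listed, 16 were measured; 9 of these were higher by the size rule and 0 lower, with a median log2 ratio of 1.26 (percentile 100). Slc25a31, which encodes the testis ADP/ATP carrier, had 0.0211 FPKM in the control and 4.02 in the mutant, and the germ cell RNA-binding protein gene Dazl (chromosome 17, 50279395 to 50293636, minus strand) had 0.0815 and 2.79 FPKM (34.3-fold, 19.2 to 70.1). The X-linked genes Xlr3a (0.347 and 5.18 FPKM) and Xlr3b (2.095 and 9.05) belong to a family of close copies, and their separate levels are uncertain. The median of this list depended on the settings: it was 0.48 when genes under 1 FPKM were kept, 0.35 among genes of at least 5 FPKM, 2.42 with a pseudocount of 0.1 and 0.35 with 5. Imprinted genes had 2 of 37 higher and 0 lower, with a median of -0.11 (percentile 0.455). Those 2 were Mest, with 48.6 and 115 FPKM, and the noncoding RNA gene H19, with 0.571 and 2.41. Kcnk9 (8.16 and 3.68 FPKM) and Meg3 (104 and 61.9) had the lowest ratios of the imprinted list. The clustered protocadherins had 0 of 56 past the size rule, with a median of 0.03 inside the random range; among genes of at least 5 FPKM it was 0.19 and above that range. Of the Hox and other patterning genes, 1 was measured, Tbx5, at 1.16 and 2.14 FPKM.

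Photoreceptor genes were compared next, by cell type and by function. Cone genes were lower in the mutant library: of 17 measured, 4 were lower by the size rule, 0 were higher, 16 lay below 0, and the median log2 ratio was -0.80 (percentile 0). The short-wave opsin gene Opn1sw (chromosome 6, 29376671 to 29388468, minus strand) had 177 FPKM in the control and 45.0 in the mutant (3.94-fold lower, 3.82 to 4.06). The other 3 were Pde6h (290 and 138 FPKM), the cone arrestin gene Arr3 (101 and 48.3) and the cone transducin gene Gnat2 (72.1 and 35.2). Rod genes had 1 of 29 lower, Guca1a (315 and 101 FPKM), 0 higher, and a median of -0.23 (percentile 0). The rod-determining transcription factor gene Nrl had 441 and 692 FPKM and its partner Nr2e3 had 273 and 443, both below the size rule. Phototransduction and visual cycle genes had 7 of 31 lower, 0 higher, and a median of -0.30 (percentile 0). The 7 were Rdh5, Rpe65 and Lrat, which this list shares with the pigment epithelium list, and Pde6h, Arr3, Gnat2 and Guca1a, given above. Photoreceptor transcription factors (0 of 21 past the rule, median -0.09) and outer segment and cilium genes (0 of 35, median -0.06) lay inside the random range.

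Retinal ganglion cell markers were lower in the mutant library by less than the size rule. All 20 measured markers had log2 ratios below 0, with a median of -0.50 (percentile 0), among them the vesicular glutamate transporter gene Slc17a6 (27.7 and 16.2 FPKM), the neurofilament genes Nefl (365 and 236) and Nefm (139 and 90.9) and the transcription factor gene Pou4f2 (5.61 and 3.36). Horizontal cell markers had 1 of 12 lower, the calcium buffer gene Calb1 (42.5 and 20.5 FPKM), and a median of -0.37 (percentile 0.01). With a pseudocount of 5 the ganglion cell median was -0.37, the horizontal cell median -0.21 and the cone median -0.54. Amacrine markers had 0 of 23 past the rule and a median of -0.20 (percentile 0.12), with the acetylcholine synthesis gene Chat at 7.41 and 3.44 FPKM. Bipolar markers had 0 of 22 past the rule and a median of 0.06, inside the random range, with Pcp2 at 229 and 386 FPKM and Lrit3 at 40.5 and 24.5. Inner retinal synapse genes had 1 of 27 lower, the glutamate receptor gene Grin2b (2.31 and 0.628 FPKM), and a median of -0.23 (percentile 0). Photoreceptor ribbon synapse genes had 0 of 24 past the rule and a median of -0.15 (percentile 0.12). Vascular markers had 1 of 19 lower, Slco1a4 (3.70 and 1.20 FPKM), and a median of -0.23 (percentile 0.2).

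Lens and pigment epithelium genes, which mark tissues next to the dissected retina, had the lowest list medians at the main settings. With a pseudocount of 5 the cone median (-0.54) lay below the pigment median (-0.52). Of 15 measured lens, cornea and ciliary body genes, 13 were lower and 0 higher, with a median log2 ratio of -3.41 (percentile 0). Cryba1 had 31.8 and 0.136 FPKM, Crybb2 had 30.2 and 0.221, and Crygs had 17.7 and 0.0976. Crygb, Crygc and Crygd are close copies in 1 cluster on chromosome 1, so their separate values are uncertain. Of 14 measured pigment epithelium and melanocyte genes, 9 were lower and 0 higher, with a median of -1.27 (percentile 0). The pigment synthesis genes Dct (19.6 and 1.48 FPKM) and Pmel (11.6 and 0.520) and the retinoid cycle genes Rdh5 (10.4 and 0.950) and Rpe65 (5.16 and 0.126) were among them. These medians also depended on the settings: for the lens list -1.68 with genes under 1 FPKM kept, -5.06 with a pseudocount of 0.1 and -1.72 with 5, and for the pigment list -0.86, -2.51 and -0.52, with -2.50 among genes of at least 5 FPKM.

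**Figure D3:**
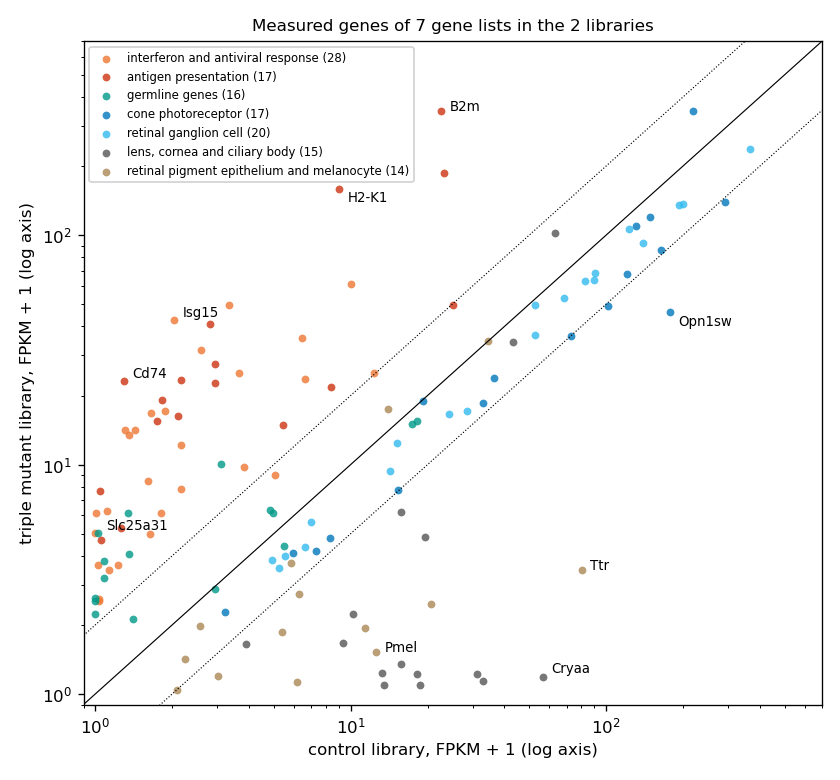
FPKM + 1 in the control library (horizontal, log axis) against the triple mutant library (vertical, log axis) for the measured genes of 7 lists, with 1 point per gene and the number of genes per list in brackets. The solid line marks equal values and the dotted lines a log2 ratio of 1 either way; B2m (21.6 and 348 FPKM) lies far above the line and Cryaa (55.7 and 0.192 FPKM) far below it.

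The remaining lists differed little between the libraries. Glycolysis and energy genes had 0 of 22 past the rule and a median of -0.12 (percentile 0.68), with the hexokinase gene Hk2 at 56.4 and 30.1 FPKM and the monocarboxylate transporter gene Slc16a1 at 70.2 and 40.0. Lipid and cholesterol synthesis genes had 0 of 20 and a median of -0.14 (percentile 0.79). Reference genes had 1 of 17 higher, B2m, and a median of 0.13 inside the random range. Gapdh, at 3.87 and 6.03 FPKM, is uncertain because many pseudogene copies share its sequence. Immediate early genes had 1 of 12 higher, Atf3 (1.84 and 4.91 FPKM), 1 lower, Dusp1 (18.7 and 7.33), and a median of 0.01 inside the random range. Unfolded protein response genes had 1 of 20 higher, also Atf3, with a median of 0.11 inside the range. Astrocyte and oligodendrocyte markers had 1 of 7 higher, Aldh1l1 (5.67 and 13.1 FPKM), with a median of 0.15 inside it. Blood genes had 1 of 5 higher and 1 lower, the near-identical globin copies Hba-a1 (3.002 and 9.56 FPKM) and Hba-a2 (9.38 and 0.0099), and a median of -0.29 (percentile 1.995). The DNA methylation machinery had a median of -0.14 (percentile 2.23). In all, 24 of 32 lists with a percentile lay outside the central 95% of random lists, 8 above and 16 below, where chance gives 1.6. The vascular, blood, apoptosis and DNA methylation machinery lists moved inside that range under at least 1 alternative. Besides the protocadherins, 4 lists inside it moved outside under 1 alternative each: outer segment and cilium (-0.10) and astrocyte and oligodendrocyte (0.29) among genes of at least 5 FPKM, the unfolded protein response in the second table (0.17) and reference genes at a pseudocount of 0.1 (0.15). The lists share genes, and genes of a list are not independent of each other.

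Genes near 0 in 1 library were counted apart, because a pseudocount understates their ratio. In the control library 41 genes were under 0.1 FPKM and at least 1 in the mutant, and 16 of these were listed at 0 in the control. Of the 41, 7 were on the interferon or antigen presentation lists, 6 on the germline list and 4 were small RNA genes. The small RNA genes Snora7a (15.1 FPKM in the mutant), Snora16a (9.28) and Snora52 (7.04), all listed at 0 in the control, were among the highest but are left out by the naming rule. By that rule the highest were the anchoring filament gene Lad1 (0.0582 and 9.67 FPKM), C4b, the class II gene H2-Aa (0.0454 and 6.67), the nucleic acid sensor gene Zbp1 (0.0113 and 5.18) and the chemokine gene Ccl12 (0.055 and 4.82). In the opposite direction 11 genes were under 0.1 FPKM in the mutant and at least 1 in the control, 4 of them listed at 0 and 3 on the lens or pigment epithelium lists. All 4 listed at 0 were small RNA genes, the highest Mir7-1 (90.3 FPKM in the control) and Mir124a-2 (72.2), which the naming rule leaves out. Crygs, Cryba2 (12.5 and 0.0987 FPKM), Crygf (4.43 and 0.0387), the paraoxonase gene Pon1 (1.94 and 0.0523) and Slc6a20a (1.63 and 0.0204) were among them, and Rprl3 was listed at 0 in the mutant.

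X-linked genes as a group lay close to 0. The 435 measured genes of chromosome X had a median log2 ratio of -0.04 (percentile 0.68), with 4 higher and 1 lower by the size rule. Of 20 chromosomes compared, 3 had medians outside the central 95% of random lists, chromosome 1 at -0.04, chromosome 7 at 0.02 and chromosome X. The share of higher genes was 4.12% on chromosome 17, which carries the H2 genes, and 0.920% on chromosome X.

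Isoform use was compared in 2419 genes with at least 2 transcripts. The share of some transcript differed by at least 30 percentage points in 22 genes, 0.909% of those compared. Transcript NM_145994 of Abi1, an actin regulator gene, held 57.1% of its gene in the control and 0.00149% in the mutant. In Stx16, which encodes a syntaxin, NM_001102423 held 17.6% and 66.4%. In Slc8a1, a sodium and calcium exchanger gene, NM_001112798 held 51.6% and 99.99%. The other 3 genes named by the rule were Emc1, Abhd14a and Kdm2b, where NM_001039200 held 2.81% and 47.3%, NM_145919 held 5.60% and 48.3%, and NM_001003953 held 60.6% and 19.3%. Transcript shares are estimates from fragments that transcripts of a gene hold in common, and without replicates their error is unknown.

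The authors' deposited table with gene symbols called 69 transcripts significant, 57 higher and 12 lower in the mutant, and 19 of them were listed at 0 in the control. Of their 69 genes, 58 passed the size rule, 17 were on the interferon or antigen presentation lists, 4 on the germline list and 2 on the lens or pigment epithelium lists. Genes called in the authors' deposited table included Prss56, B2m, H2-K1, Bst2, Irgm1, Oasl2, Ifit1, Crym, Opn1sw, Guca1a, Ttr, Rgr and Dct. In the authors' deposited table the smallest p was 5e-05, held by 53 of the called rows, and their q ran from 0.0184 to 0.0425. The authors' deposited table did not call Edn2 (q = 0.948), Cryaa (q = 0.615), Fgf2 (q = 0.0627) or Isg15 (q = 0.0769). None of the Dnmt1, Dnmt3a and Dnmt3b transcripts was called in the authors' deposited table; the main Dnmt3a transcript, NM_007872, had q = 0.999. With 1 library per genotype, those values rest on a spread that no replicate of either genotype measured.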

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

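The tests of microglia number, of genes outside chromosome 17 and of the per-gene readings of the lens and pigment lists were chosen after the result was seen. The other tests were written before their values were seen, but some genes of the lens test were already on the fixed lens list.

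The table without symbols holds 3059 rows whose transcript is not in the other table, and 34 of the 933 with at least 1 FPKM were higher in the mutant library by the size rule, while 30 were lower. A transcript of Gbp3, an interferon-induced GTPase gene, had 0.802 FPKM in the control and 13.8 in the mutant. Transcripts of Rcan2 (0.0136 and 5.77 FPKM) and Tnk2 (0.166 and 6.41) followed, apart from a microRNA. In the other direction, Mir6516 had 57.2 FPKM in the control and was listed at 0 in the mutant. FPKM is unstable for so short an RNA. A transcript of Cryaa had 56.8 and 0.242 FPKM, and a transcript of Gngt2 had 4.13 and was listed at 0. These are single transcripts, and a shift between transcripts of the same gene was not excluded: of 2 Chtop transcripts, NM_001293779 had 0.0387 and 4.40 FPKM and NM_001293778 had 5.86 and 1.22.

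Interferon and antigen presentation genes were higher together with microglia markers. More microglia at constant expression per cell could raise both alike. But the median log2 ratio of 44 interferon and antigen presentation genes was 2.55 against 1.23 for 20 microglia markers, a gap of 1.32. Resampling list members, as if they were independent of each other, gave this gap a 95% range of 0.779 to 2.05. Such a range covers the choice of listed genes only, not variation between libraries or animals. The bound used was 0.133, the half-width of the central 95% of medians of random lists matched to the 20 microglia markers alone. No random range was drawn for the gap itself. The gap depended on the pseudocount, at 2.12 (1.55 to 2.86) with 0.1 and 0.703 (0.215 to 1.31) with 5, and lay above 0 in each. Lymphocyte genes were higher in the mutant in sum (1.60 and 3.56 FPKM over 20 genes), with Cd8b1 and Nkg7 listed at 0 in the control and at 0.197 and 0.2997 FPKM in the mutant, so a few lymphocytes are not excluded; but 0 of the 20 reached 1 FPKM in either library, which argues against them as the main source. A difference of the major histocompatibility region between the animals would leave other chromosomes alone, but the 31 genes outside chromosome 17 had a median of 2.40. A response to loss of the methyltransferases may remain, as may an infection, a difference of strain (the labels differ, which may be an entry error) or another condition of the mutant animals, which 1 library per genotype cannot separate.

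Lens and pigment epithelium genes were lower in the mutant library, and neighbouring tissue carried into the control dissection is a candidate explanation. A list of 14 lens genes that are not crystallins, of which the control retina had 5 at 1 FPKM or more, summed to 103% of the control in the mutant, past the bound set beforehand against carry-over. That bound was poorly chosen, since Tdrd7 (109 and 119 FPKM) alone held 87.1% of the sum and would hide a small share of lens. Read per gene, 12 of 13 were lower, and the median stood at 42.8% of the control. This list is not independent of the pattern, because Mip, Lim2, Bfsp1, Bfsp2 and Lgsn were also on the fixed lens list. All of these were lower, and Bfsp2 was already among the lower genes of the fixed list. A further list of 16 pigment epithelium genes, 13 of them at 1 FPKM or more in the control, had a median log2 ratio of -0.13, also past its bound, but its members went both ways (Tspan10 at 1.67 and 0.176 FPKM, Krt18 at 36.7 and 53.05): 10 of 16 were lower, and the per-gene median of 75.5% was just past its own bound of 75% against carry-over, with quartiles of 39.8% and 123%. Loss within the Cre lineage as the only cause was tested with the same sum of 103%. That test assumed that the retinal Cre does not reach the lens, which was not checked here. Under that assumption, such loss alone would leave lens genes unaltered. Yet 13 of 15 measured lens, cornea and ciliary body genes were lower. For the pigment genes, and for lens genes without that assumption, carry-over and loss within the Cre lineage cannot be told apart here. With 1 library per genotype, both follow the groups, the lens sum rests on Tdrd7 and the pigment members disagree. These grounds for leaving the question open were set after the values were seen.

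Germline genes were higher at low levels in the mutant library. Against counting noise at low levels as the cause, at most 0 list members passed the size rule in 100 simulated pairs of unaltered libraries. In the data 9 passed. The simulated pairs held counting error only, so variation between libraries or animals was not addressed. The counting interval of the fold lay above 2 in 6 of the 9 genes. The others, Mael, Fkbp6 and Xlr4a, were listed at 0 in the control and thus had no interval. Of 15 abundant testis transcripts, 1 reached 1 FPKM in the mutant, Meig1, at 4.05 FPKM in the control and 4.41 in the mutant, while Prm1 had 0.431 and 0.151. That list rests mostly on late spermatid genes, so RNA of earlier germ cells remains open. Loss of DNA methylation at these genes may be the cause, but methylation was not measured here.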

How the results depend on the processing

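Alternatives without lens and pigment genes, without immune genes, and without small RNA genes were chosen after seeing the data. No paired analysis was possible because each genotype had 1 library and no test was run. Counts of higher and lower genes were 245 and 86, and moved to 390 and 180 with a pseudocount of 0.1, 92 and 33 with 5, 156 and 56 with a filter of 5 FPKM, and 80 and 25 with a log2 limit of 2; fewer genes or a stricter limit are built into the last 2. They were 245 and 86 centred on the median, 240 and 87 rescaled without the 50 highest genes, 263 and 74 in the second table, 245 and 64 without lens and pigment genes, 190 and 86 without immune genes and 240 and 79 without small RNA genes. Genes near 0 in the control were 41, and 16 when exactly 0 was asked; those near 0 in the mutant were 11, with 19 for under 0.5 against at least 2 FPKM and 4 for exactly 0. Isoform use gave 22 genes, 4 with a summed FPKM of at least 20 and 1 with a limit of 50 points. The log2 ratio of Dnmt3a was -0.63, and -0.57 in the second table, whose scaling shifts ratios by 0.06; Dnmt3b fell under the filter there. The authors' 69 calls became 0 at q of at most 0.01. That outcome was fixed, since their smallest p of 5e-05, held by 53 rows, gave a q of 0.0184. It therefore says nothing about how firm the calls are. Across 7 settings, 196 of 223 list medians moved by less than the spread of random lists, 27 moved by more and 0 of those outside the random range reversed. Centring removed a median of only -2.0e-06, and rescaling shifted the mutant by only -0.012 on the log2 scale. Those settings could hardly move a median past that spread, so the tally overstates stability. The immediate early median, inside the random range, went from 0.01 to -0.00096 when rescaled. Of the lists, 20 of the 24 outside the random range stayed outside with the same sign. The other 4 were vascular, blood, apoptosis and DNA methylation machinery genes. X-linked genes kept a median between -0.04 and -0.02. Depth limits genes under about 0.031 FPKM at 2 kb in the control, and no alternative supplies the missing replicates.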

Other observations

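Both libraries carried transcripts of the Y-linked genes Ddx3y (14.3 FPKM in the control and 16.1 in the mutant), Kdm5d (7.00 and 7.08), Uty (6.38 and 6.28) and Eif2s3y (17.1 and 21.7). Xist, which is transcribed from the inactive X chromosome, had 0.0058 FPKM in the control and 0.234 in the mutant, from about 4.99 and 235 recovered fragments. These genes were chosen after their values were seen.

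The authors' calls and the size of the difference did not rank transcripts alike. A transcript can differ widely through a swap within its gene: in Abi1, NM_145994 had 12.1 and 0.000334 FPKM and NM_001077190 had 0.000896 and 12.8. Transcripts were taken with a value above 0 in both libraries, a difference of at least 32-fold and at least 5 FPKM in 1 library. Of these 32 transcripts, the authors' deposited table called 2. It also called 11 transcripts that stayed under 1 FPKM in both libraries, all 11 listed at 0 in the control, the lowest at 0.2999 FPKM in the mutant.

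Crystallin genes of the alpha, beta and gamma families, measured or not, summed to 303 FPKM in the control and 51.0 in the mutant. Of the 17 measured, 15 were lower by the size rule. Of 11 interferon genes looked up after the interferon response was seen, 0 were measured, and their sum was 0.051 FPKM in the control and listed at 0 in the mutant.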
